A study of Mus musculus with 9 samples.

How the data were processed

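RNA immunoprecipitation followed by sequencing (RIP-seq) was carried out on whole healthy liver of 8-week-old C57BL/6 mice. Per the labels, 9 libraries were made: 3 from pull-downs with an antibody against HuR, 3 from pull-downs with control IgG, and 3 from Input, the RNA of the lysate. HuR, the product of Elavl1, is an RNA-binding protein that binds U-rich and AU-rich stretches. Per the labels' protocols, the pull-downs were native, each used a single liver, and libraries were prepared with a total RNA kit for Ion sequencers. Per the submitters' processing notes, reads were processed with Bowtie2 and featureCounts on the mm10 genome. The versions of Bowtie2 and featureCounts are not given in the sources used here.

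The deposited file is a table of 388562 lines covering 210966 distinct exons of 33732 gene names. Its values per library are RPKM (reads scaled by exon length and library depth) computed by the authors. The Input column holds the mean RPKM of the Input libraries, as deposited, and none of the 3 Input libraries has a column of its own. The fold columns are log2 ratios by the authors, per library, of RPKM plus 1 over Input plus 1. The table also holds a deposited p-value and a deposited q-value per exon for HuR against IgG, whose test and adjustment are not given in the sources used here. In the deposited table, numbers of 1 or more had lost their decimal mark. Each number was restored from its digits and checked against the authors' fold columns. Of 138826 distinct lines of values, 138761 matched in all 6 folds, 65 in 5 of them, and 0 had more than 1 possible reading. The fold columns are numbered in the order of the RPKM columns in the file, which exchanges HuR 2 and HuR 3 relative to the RPKM column names; the RPKM column names were followed.

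Reads that overlap several listed exons were split between them, as the values show, so exon values were multiplied by exon length, summed per gene over all lines and divided by the length of the gene's merged exons. This gave gene RPKM. From the fixed step between values, the library sizes behind the RPKM were 26.6, 26.3 and 26.9 M reads for HuR 1, 2 and 3, and 15.9, 26.7 and 28.8 M reads for IgG 1, 2 and 3 (M, mega). Between 85.2% and 89.2% of gene sums were whole reads within 0.05 of a read. The Input depth is unknown. Of the listed exons, 98.1% were found at the same coordinates in GENCODE M21 (GRCm38, the assembly also called mm10), which gave gene positions and classes. Of the gene names, 32909 were in that annotation and 82 were carried by more than 1 gene ID. The table has 0 lines for the mitochondrial genome.

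HuR RIP was compared with IgG RIP by limma 3.58.1 in R 4.3.3, with trend and robust moderation, on log2(RPKM + 0.5). Genes were kept at an RPKM of 0.5 or more in at least 3 of the 6 RIP libraries, which left 5510. Tests were two-sided, Benjamini-Hochberg adjusted, with a threshold of 0.05. The plan had been a model of all 9 libraries, with a count model if read counts could be had. As Input is only a mean, it gave no replicate, and the Input comparisons are values without a test. As the values are RPKM with reads split between exons, no count model was used. A gene was called HuR-associated when it was past the threshold against IgG RIP and above the Input mean in all 3 HuR libraries. In place of the planned test against Input, this is a weaker rule.

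Before the data were examined, 38 gene lists, the comparisons and most alternatives were fixed. Lists with at least 5 tested members were tested with limma camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. A rule fixed at the same time chose the genes named in each comparison. It took the 10 largest changes per direction past the threshold whose groups did not overlap and whose higher group averaged 5 RPKM or more, leaving out predicted (Gm number), Rik and pseudogene names and small nuclear and small nucleolar RNA genes. It added up to 4 members of each list described, by smallest p, and Elavl1, Cycs, Ndufb6, Uqcrb, Apob, Actb, Malat1 and Alb whatever their values. Not every gene chosen by the rule is named in the text. For comparisons with Input, which have no test, the largest differences among genes with all 3 libraries on the same side of the Input mean were taken. For 4 motifs, UUUUUUU, UUUAUUU, AUUUA and UAUUUAU, counts in the longest annotated 3' UTR of called genes were compared with tested genes drawn from the same bin of 5 for expression and of 5 for 3' UTR length, in a permutation test of 100000 resamples. Nuclear copies of mitochondrial genes were found with blastn 2.17.0, at an e-value of 1e-20 and an aligned share of at least 50%. The last-exon share was computed for genes with at least 3 exons. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

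The alternatives were other scalings, no filter and a stricter filter (1 RPKM), pseudocounts of 0.1 and 1, no trend, sample quality weights, a replicate block, protein-coding genes only, and each RIP library left out in turn. After the data were examined, voom on reads recovered from the RPKM values, each exon counted once, centring at the median, 2 libraries left out together, the list tests under other scalings or with protein-coding genes only, a wider gene set for the motifs, the last-exon share, and the tests of small nucleolar RNA against small nuclear RNA and, per library, against all genes were added. The comparison was tested on simulated data made from these libraries, with 200 of the 5510 genes changed. It recovered 7% of 100 genes changed by 2 on the log2 scale and 67% of 100 genes changed by 4, with 3 false calls among 5310 unchanged genes. Noise was drawn independently for each gene and library, with no general shift. The false calls therefore do not cover a general shift or correlation between genes, both of which the real data hold.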

Results

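The RNA held by HuR in mouse liver was compared with the RNA held by a control IgG and with the RNA of the lysate (Input). Each group had 3 libraries, and Input was available only as the mean of its 3 libraries. The series states its purpose as finding the RNAs that HuR targets in this tissue. The library sizes behind the RPKM values were 26.6, 26.3 and 26.9 M reads in HuR 1, 2 and 3, and 15.9, 26.7 and 28.8 M reads in IgG 1, 2 and 3. Between 27.9% (HuR 2) and 60.5% (HuR 3) of those reads lay in listed exons. The number of exons above 0 was 47314, 51073 and 58706 in the HuR libraries and 62224, 46814 and 25451 in the IgG libraries, against 107754 for the Input mean. Reads are not independent molecules, so depths cover counting error only.

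Ribosomal and other structural RNA took a large part of the reads in listed exons. The 3 genes that cover the ribosomal repeat took 47.2%, 42.6% and 31.8% of listed reads in HuR 1, 2 and 3, against 31.2%, 63.3% and 64.8% in IgG 1, 2 and 3 and 73.4% in the Input mean. Protein-coding genes took 23.5% ± 8.83 (SD, n = 3) of listed reads in HuR RIP and 13.7% ± 4.30 (SD, n = 3) in IgG RIP (exact permutation p = 0.2, two-sided), against 14.3% in the Input mean. Some libraries stood apart. Small nuclear RNA took 45.9% of listed reads in HuR 3, against 8.74% and 4.57% in HuR 1 and 2. Small nucleolar RNA took 18.1% in IgG 1, against 3.598% and 4.06% in IgG 2 and 3. Unprocessed pseudogenes took 0.658% ± 0.183 (SD, n = 3) in HuR RIP and 0.0628% ± 0.0336 (SD, n = 3) in IgG RIP (exact permutation p = 0.1, the smallest that 3 against 3 libraries allow).

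HuR RIP against IgG RIP asks which RNAs the HuR antibody held beyond non-specific carry-over. Among the RNAs higher with HuR were those of the liver genes Rida, Cfhr2 and Ttpa. Higher too were those of Cox7a2l, Ndufc2 and Atp5e, nuclear genes of mitochondrial proteins. Small nucleolar RNAs and a 5S ribosomal RNA copy were among the RNAs lower with HuR. The median of all 5510 tested genes was itself higher by 0.92 on the log2 scale (SE over libraries 0.36), with 79.1% of genes positive, and single changes are best read against that shift. limma called 37 genes higher and 7 lower, and 0 and 0 with the replicate number as a block (1665 higher and 238 lower at an unadjusted p under 0.05). Of the 37, 21 were protein-coding, 7 were pseudogenes and 9 were antisense or other non-coding genes. All 7 lower genes were structural RNA, 6 of them small nucleolar RNAs.

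The largest change past the threshold among named genes was that of Rida, which encodes an enzyme that clears reactive imines (chromosome 15, 34484021 to 34495255). Its level was 20.03 ± 1.64 RPKM in HuR RIP and 0.599 ± 0.641 RPKM in IgG RIP (SD, n = 3 each), a log2 fold change of 4.38 (SE 0.80, adjusted p = 0.0196), with 0.811 RPKM in the Input mean. Cfhr2, a gene of the complement factor H family on chromosome 1, reached 34.3 ± 23.9 RPKM against 1.83 ± 2.91 RPKM, a log2 fold change of 4.36 (SE 0.96, adjusted p = 0.0462). Cd59a, which encodes an inhibitor of the complement membrane attack complex, rose by 3.69 (SE 0.82). Ttpa, the alpha-tocopherol transfer protein, rose by 3.31 (SE 0.80), from 0.842 to 10.6 RPKM. Among nuclear genes of mitochondrial proteins, Cox7a2l, which takes part in assembling respiratory supercomplexes, rose by 3.66 (SE 0.81), from 1.02 to 17.3 RPKM. Urad, an enzyme of uric acid breakdown, rose by 3.39 (SE 0.73). Cnbp, which encodes a nucleic acid binding protein, rose by 3.41 (SE 0.83). Ceacam1, a cell adhesion gene, rose by 3.33 (SE 0.75), and Tmem220, a membrane protein gene, by 3.35 (SE 0.77). Relative to the median of all genes, these 9 rose by 2.39 (Ttpa) to 3.46 (Rida). With libraries centred at their medians, limma called 1 gene higher, Rida, and 18 lower, so that the other 8 were no longer past the threshold. Each was above the Input mean in all 3 HuR libraries.

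In the other direction, n-R5s71, a copy of 5S ribosomal RNA (chromosome 11, 74319792 to 74319910), was 1.78 ± 1.62 RPKM in HuR RIP, 26.9 ± 14.6 RPKM in IgG RIP (SD, n = 3 each) and 14.6 RPKM in the Input mean. Its log2 fold change was -3.83 (SE 0.91, adjusted p = 0.0464). The small nucleolar RNA AF357425 was listed at 0 in all 3 HuR libraries and at 12.6 ± 14.6 RPKM in IgG RIP (SD, n = 3; adjusted p = 0.0367). Among predicted genes, which the rule for naming left out, Gm23734, a small nucleolar RNA gene, was at 4.58 RPKM in HuR RIP and 294 RPKM in IgG RIP.

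**Figure D1:**
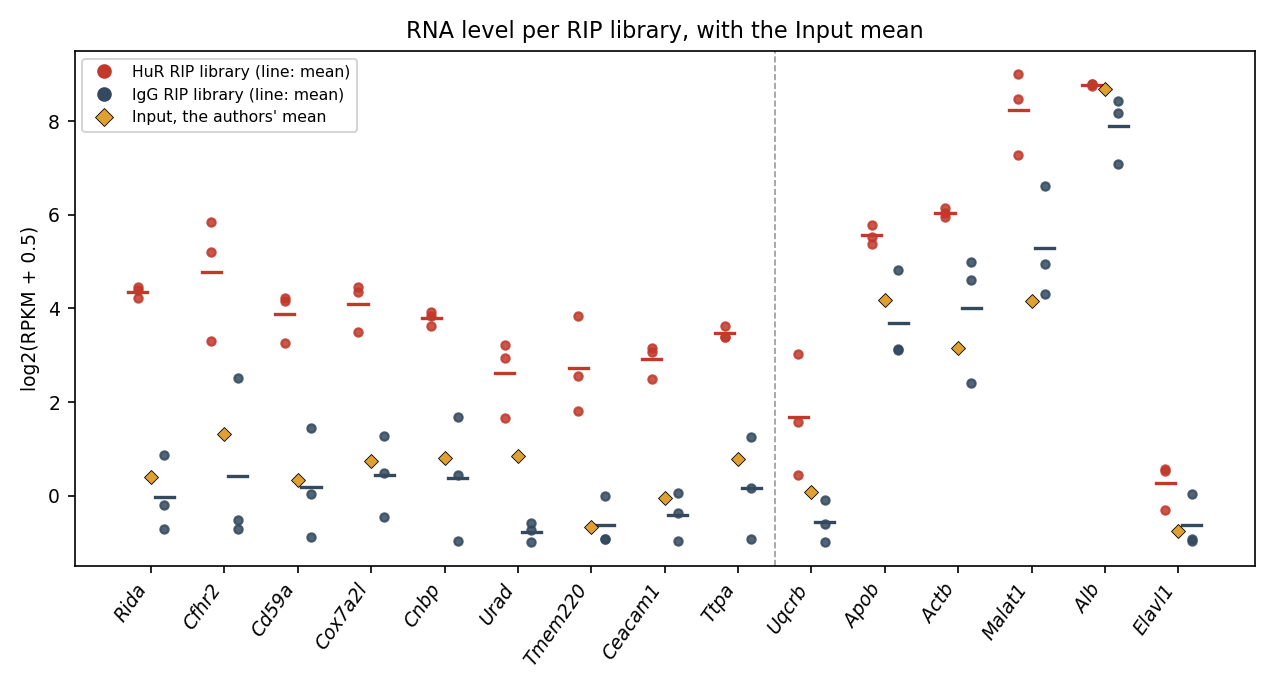
RNA level of named genes in each RIP library (points; short lines are group means) and in the Input mean (diamonds), as log2(RPKM + 0.5); left of the dashed line the 9 increases described above, right of it genes named whatever their values. All 3 HuR points of Rida lie above its IgG points, whereas the groups differed by less for Elavl1.

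Genes followed whatever their values did not pass the test. Elavl1, the gene of HuR itself, was at 0.748 ± 0.385 RPKM in HuR RIP and 0.187 ± 0.291 RPKM in IgG RIP (SD, n = 3 each), a log2 fold change of 0.88 (SE 0.51, adjusted p = 0.228) that turned to -0.22 with libraries centred at their medians. Malat1, a nuclear long non-coding RNA, was at 341 ± 180 RPKM against 49.1 ± 42.4 RPKM, with a log2 fold change of 2.96 (adjusted p = 0.0959). Actb, the gene of beta-actin, had a log2 fold change of 2.04 (adjusted p = 0.178), Uqcrb 2.25 (adjusted p = 0.0759) and Apob 1.87 (adjusted p = 0.192). Alb, the gene of serum albumin, was at 439 ± 7.39 RPKM against 257 ± 109 RPKM (SD, n = 3 each). Its log2 fold change was 0.88 (adjusted p = 0.546), which turned to -0.75 under TMM-like scaling and to -0.22 under centring. This gene level includes the last exon of Alb, which was at 5341, 1313 and 6058 RPKM in HuR 1, 2 and 3. In IgG 1, 2 and 3 that exon was at 75.4, 17.8 and 236 RPKM. The close values of the HuR libraries therefore hold for the gene sum and not along the gene. Cycs and Ndufb6 were below the filter, at 0.797 and 0.462 RPKM in HuR RIP and 0.0320 and 0.171 RPKM in IgG RIP.

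Among lists fixed beforehand, major urinary protein genes, which encode pheromone-binding proteins secreted by the liver, lay highest. Their 20 tested members had a median log2 fold change of 2.95, and camera placed them above other genes (adjusted p = 0.00839, but adjusted p = 0.876 with an estimated correlation). No single member passed over all genes, whereas 17 passed when adjusted over the list alone. The estimated correlation between members was 0.944, so these are not 17 separate results. Of the 20 members, 0 lay above the Input mean in all 3 HuR libraries. Their median level was 283, 20.8 and 643 RPKM in HuR 1, 2 and 3, against 35.9, 12.1 and 16.9 RPKM in IgG 1, 2 and 3 and 36.7 RPKM in the Input mean. HuR 2 was also the library with the highest Xist, at 10.2 RPKM. The list's call ended without HuR 3 (adjusted p = 0.305) and without IgG 1 (adjusted p = 0.238). Mup10 was at 338 ± 298 RPKM against 20.1 ± 13.2 RPKM (SD, n = 3 each), with a log2 fold change of 3.40 (adjusted p = 0.0837).

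Lists of genes whose proteins regulate RNA had medians above the shift. The list of AU-rich element and 3' UTR binding proteins had 24 tested members with a median of 1.36, and camera placed it above other genes (adjusted p = 0.0165, but adjusted p = 0.876 with an estimated correlation). Splicing factors had 29 tested members with a median of 1.29 and the same adjusted p values, 0.0165 and 0.876. In both lists 0 members passed over all genes and 0 when adjusted over the list alone; 19 of 24 and 23 of 29 lay above the median of all genes, and all were above the Input mean in all 3 HuR libraries. Examples are Ybx1 with a log2 fold change of 2.39 (adjusted p = 0.0700), Pcbp2 with 2.13 (adjusted p = 0.0844), Zfp36l1 with 2.06 (adjusted p = 0.0945), Celf1 with 2.08 (adjusted p = 0.0981), Srsf3 with 2.06 (adjusted p = 0.0623), and Hnrnpu with 2.16 (adjusted p = 0.0747). The first call ended without IgG 3 (adjusted p = 0.0636). The call for splicing factors ended without HuR 1 (adjusted p = 0.115), HuR 2 (adjusted p = 0.0932) or IgG 2 (adjusted p = 0.1), and under centring (adjusted p = 0.0607). Both calls ended under quantile normalization (adjusted p = 0.102 and 0.0857) and with protein-coding genes only (adjusted p = 0.210 and 0.299), where the small RNAs are not among the other genes. They also ended with HuR 3 and IgG 1 both left out (adjusted p = 0.122 and 0.254).

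Published HuR target mRNAs, 16 of them tested, had a median log2 fold change of 1.11, and camera did not place them apart from other genes (adjusted p = 0.240). None passed over all genes and 3 did when adjusted over the list alone. Mcl1, an inhibitor of apoptosis, was at 7.80 ± 3.69 RPKM against 0.678 ± 0.869 RPKM (SD, n = 3 each), with a log2 fold change of 2.95 (adjusted p = 0.0566). Cdc42 had 2.68 (adjusted p = 0.0683), Atg5 2.23 (adjusted p = 0.0835) and Ccnd1 1.41 (adjusted p = 0.127). The 7 tested members of the list of targets published in liver cells had a median of 1.87 (camera adjusted p = 0.240), with 0 past the threshold over all genes and 2 when adjusted over the list alone. Mat2a, of that list, had a log2 fold change of 1.5 (adjusted p = 0.146).

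Lists of liver metabolism held few calls over all genes. Of 54 tested genes of the nuclear-encoded respiratory chain and ATP synthase, 2 rose over all genes and 9 when adjusted over the list alone, with a list median of 1.08 (camera adjusted p = 0.542). Ndufc2, a subunit of complex I, rose by 3.02 (SE 0.72, adjusted p = 0.0483) and Atp5e, a subunit of ATP synthase, by 3.09 (SE 0.75, adjusted p = 0.0483). Sdhd had a log2 fold change of 2.90 (adjusted p = 0.0620) and Cox7c 2.46 (adjusted p = 0.0623). Among 53 cytochrome P450 and conjugation enzymes, 0 passed over all genes and 13 when adjusted over the list alone (median 1.47, camera adjusted p = 0.214, but 0.0223 under centring). Examples are Sult1d1 with 2.91 (adjusted p = 0.0566), Cyp2c50 with 3.07 (adjusted p = 0.0617), Ugt2b1 with 3.10 (adjusted p = 0.0659) and Ugt2b5 with 3.12 (adjusted p = 0.0700). Of 24 genes of fatty acid oxidation, 5 passed when adjusted over the list alone (median 1.21, camera adjusted p = 0.191, but 0.0259 without HuR 1), with Etfa at 3.33 (adjusted p = 0.0566), Acadl at 2.77 (adjusted p = 0.0566), Cpt1a at 2.73 (adjusted p = 0.0659) and Acadm at 2.66 (adjusted p = 0.0659). Of 23 genes of cholesterol synthesis, 4 passed when adjusted over the list alone (median 1.57, camera adjusted p = 0.176, but 0.0344 under centring and 0.00901 with HuR 3 and IgG 1 both left out), with Ebp at 2.82 (adjusted p = 0.0700), Idi1 at 2.39 (adjusted p = 0.0737), Hmgcs1 at 2.70 (adjusted p = 0.0758) and Msmo1 at 2.25 (adjusted p = 0.0815). With all libraries and an estimated correlation, camera gave an adjusted p of 0.876 for cytochrome P450 enzymes, fatty acid oxidation and cholesterol synthesis alike. Plasma proteins and apolipoproteins, 26 of them tested, had a median of 1.04 (camera adjusted p = 0.608), with 0 past the threshold by either adjustment. Among them Apoc2 had 2.16 (adjusted p = 0.0990), Azgp1 1.86 (adjusted p = 0.156) and Apoc3 2.01 (adjusted p = 0.180).

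Small nucleolar and Cajal body RNAs, which guide modification of ribosomal and spliceosomal RNA, lay lowest. Their 129 tested members had a median log2 fold change of -1.70, which is 2.62 below the median of all genes, and camera placed them below other genes (adjusted p = 6.2e-43, but adjusted p = 0.876 with an estimated correlation). Over all genes 1 member fell, and 3 fell when adjusted over the list alone. Snord82 was at 7.46 ± 9.82 RPKM against 108 ± 108 RPKM (SD, n = 3 each), with a log2 fold change of -4.53 (adjusted p = 0.0566). Snord14e had -4.06 (adjusted p = 0.0566) and Snord87 -3.86 (adjusted p = 0.0623). Median levels were 89.4, 35.1 and 37.8 RPKM in HuR 1, 2 and 3, against 669, 88.0 and 59.8 RPKM in IgG 1, 2 and 3, so that IgG 1 stood apart. Without IgG 1 the list's median was -0.62, or 1.98 below that of all genes, and camera still placed it below other genes (adjusted p = 1.1e-28).

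Genes with exons over small nucleolar RNAs went the same way by their medians, though not all did. Apart from ribosomal protein genes, 29 protein-coding genes with such an exon had a median of -0.61, with 5 of them above the median of all genes. Phb2, which has such an exon, was at 61.6, 64.9 and 27.0 RPKM in HuR 1, 2 and 3 and at 9.45, 5.63 and 2.34 RPKM in IgG 1, 2 and 3. The 13 long non-coding host genes had a median of -1.05 (camera adjusted p = 3.7e-05, but adjusted p = 0.876 with an estimated correlation), with 0 past the threshold over all genes and 1 when adjusted over the list alone. The 11 with an exon over a small nucleolar RNA gene had a median of -1.09, and the 2 without one, Snhg11 and Epb41l4aos (the latter named after its values were seen), had a median of 0.89, or 0.03 below that of all genes. IgG 1 stood apart here too: median levels were 16.0, 3.69 and 2.57 RPKM in HuR 1, 2 and 3 and 51.6, 8.77 and 3.92 RPKM in IgG 1, 2 and 3. Without IgG 1 the camera adjusted p was 0.00276. Snhg3 was at 1.6 ± 0.972 RPKM against 23.1 ± 25.2 RPKM (SD, n = 3 each; log2 fold change -2.95, adjusted p = 0.0700). Snhg8 had -2.47 (adjusted p = 0.134), Snhg1 -2.10 (adjusted p = 0.2) and Snhg11 0.97 (adjusted p = 0.206), the last turning to -0.13 under centring. The 51 cytosolic ribosomal protein genes had a median of -0.01 and lay below other genes (camera adjusted p = 1.2e-04, but adjusted p = 0.876 with an estimated correlation), with 0 past the threshold by either adjustment. Their median level was 5.24 RPKM in IgG 1, against 1.44 and 1.27 RPKM in IgG 2 and 3, and without IgG 1 the camera adjusted p was 0.00148. The call ended with HuR 3 and IgG 1 both left out (adjusted p = 0.102). Of them, 20 have an exon over a small nucleolar RNA gene, with a median of -1.28, and 31 have none, with a median of 0.73. Rps2, with such an exon, had a log2 fold change of -2.92 (adjusted p = 0.0993) and Rpl13, also with one, -2.34 (adjusted p = 0.123). Rps21, without one, had 2.47 (adjusted p = 0.0574) and Rpl35a 1.15 (adjusted p = 0.120).

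Spliceosomal and other small nuclear RNAs, 22 of them tested, were placed below other genes by camera (adjusted p = 6.6e-04, but adjusted p = 0.876 with an estimated correlation), with 0 past the threshold by either adjustment. Their median was 0.58 and their mean -0.23, of opposite sign. The call ended under quantile normalization (adjusted p = 0.973) and with HuR 3 and IgG 1 both left out (adjusted p = 0.412). Median levels were 1281, 549 and 581 RPKM in HuR 1, 2 and 3 and 1275, 250 and 407 RPKM in IgG 1, 2 and 3. The 4 members named by smallest p were the U3 copies Rnu3b1, Rnu3b2, Rnu3b3 and Rnu3b4, a small nucleolar RNA in function, with log2 fold changes of -2.63, -2.64, -2.63 and -2.65 (adjusted p = 0.114, 0.113, 0.114 and 0.112). Reads of such copies cannot be assigned to a single gene.

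**Figure D2:**
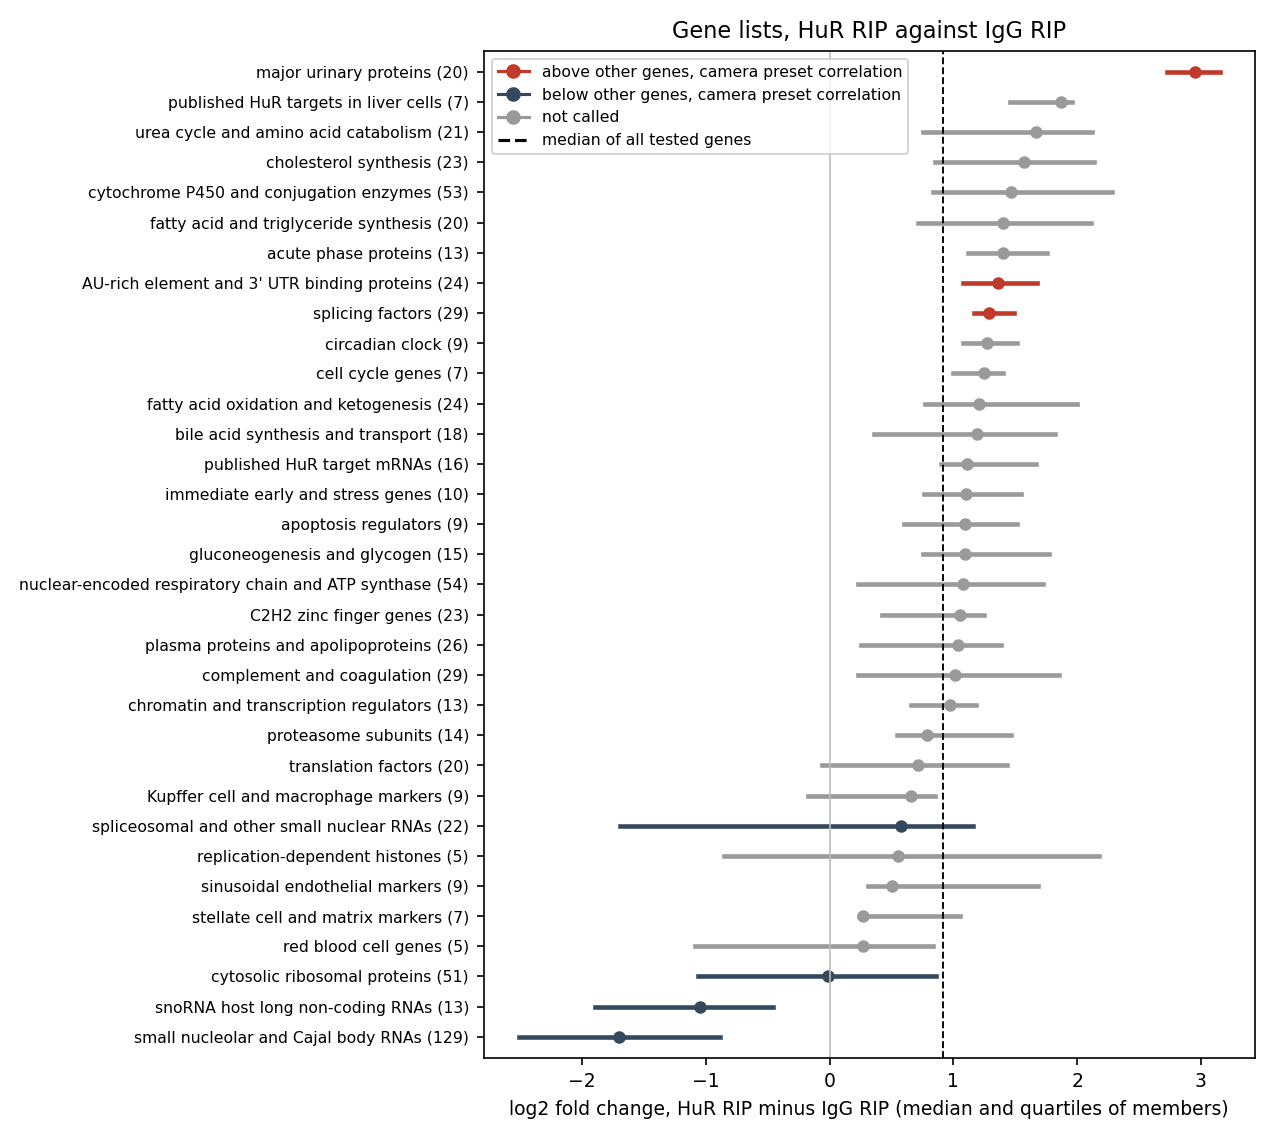
Median (points) and quartiles (bars) of the log2 fold change of the tested members of each list, HuR RIP minus IgG RIP, with the number tested in parentheses; colours give camera calls at the preset correlation and the dashed line the median of all tested genes. Major urinary proteins lie highest, with a median of 2.95, and small nucleolar RNAs lowest, with a median of -1.70.

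Markers of the other cells of a whole liver were not placed apart from other genes by camera. Kupffer cell and macrophage markers, 9 of them tested, had a median log2 fold change of 0.65 (camera adjusted p = 0.536) and sinusoidal endothelial markers, also 9, a median of 0.50 (camera adjusted p = 0.944). None of the former and 1 of the latter passed when adjusted over the list alone. Lyz2 had 1.95 (adjusted p = 0.117), C1qa 1.25 (adjusted p = 0.380), Vsig4 0.85 (adjusted p = 0.326) and Csf1r 0.76 (adjusted p = 0.375). Fcgr2b had 2.19 (adjusted p = 0.0759), Ptprb 1.84 (adjusted p = 0.115), Dnase1l3 1.68 (adjusted p = 0.122) and Eng 1.10 (adjusted p = 0.238). Under centring, Vsig4 turned to -0.25, Csf1r to -0.34 and Eng to -0.0024; under quantile normalization Csf1r turned to -0.28, and under TMM-like scaling C1qa to -0.0018. Lymphocyte and neutrophil markers had 0 genes above the filter.

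The call of single genes rested on few libraries. Against 37 higher and 7 lower, limma called 7 and 4 without HuR 1, 18 and 9 without HuR 2, 11 and 9 without HuR 3, 1761 and 28 without IgG 1, 42 and 30 without IgG 3, and 0 and 0 without IgG 2 (844 higher and 206 lower at an unadjusted p under 0.05). At that unadjusted level 1539 genes were higher and 176 lower with all libraries, and the libraries of the groups did not overlap for 34.8% of tested genes (1725 higher and 192 lower). Chance gives 10% without a general shift, but here the library medians did not overlap either. The balance at the unadjusted level depended on the scaling. It stayed toward HuR RIP with scaling without structural RNA (1066 higher and 412 lower), was level under quantile normalization (538 and 539), and turned with libraries centred at their medians (271 and 802) and under TMM-like scaling (313 and 756). The last 3 set the libraries to a common level, which largely removes a general shift by construction.

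The authors' deposited test per exon gave a lowest q-value of 0.110, shared by 71 exons, and 0 of 136082 exons with a q-value under 0.05. Their p-value was under 0.05 for 3200 exons, 2845 of them higher in HuR RIP and 355 lower.

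HuR RIP against Input asks what the pull-down enriched over the RNA present in the lysate. Of 6018 genes, 3799 were above the Input mean in all 3 HuR libraries and 540 were below it in all 3. The median gene was above Input by 1.26, 1.21 and 1.002 on the log2 scale in HuR 1, 2 and 3, and with each library centred at its median the counts were 1555 and 1571. Rpl12 was above Input by 4.87 ± 1.27 (SD, n = 3, log2) and Phb2, a gene of the mitochondrial prohibitin complex, by 4.62 ± 0.70. Both genes have exons over small nucleolar RNA genes. Cyb5r3, the gene of cytochrome b5 reductase, has none and was above Input by 4.37 ± 0.25, at 73.2 RPKM against 3.03 RPKM. Ppp1cb averaged 4.58 ± 4.64 above Input, with 599 RPKM in HuR 3 against 1.67 and 1.88 RPKM in HuR 1 and 2. Below Input were copies of 5S ribosomal RNA, such as n-R5s41 by -3.19 ± 0.41, n-R5s71 by -3.15 ± 1.55 and n-R5s56 by -2.83 ± 0.91. Lars2, the gene of mitochondrial leucyl-tRNA synthetase, was at 869 RPKM against 6730 RPKM, a difference of -3.02 ± 0.55. The scaling without structural RNA counted Lars2 among the structural RNA genes. Whether its reads are mRNA of the enzyme was not tested. These are values without a test, since Input had no replicates of its own.

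IgG RIP against Input describes what the control antibody took or lost. Of the same 6018 genes, 1138 were above the Input mean in all 3 IgG libraries and 728 below it in all 3, and with each library centred at its median the counts were 1336 and 1311. The median gene differed from Input by 0.84, -0.13 and -0.25 in IgG 1, 2 and 3. Among the genes furthest above Input were genes with exons over small nucleolar RNAs, namely Snhg8 by 5.53 ± 1.91 (SD, n = 3, log2), Rpl6 by 5.17 ± 1.46, Ptcd3 by 5.15 ± 1.99 and Rpl27a by 4.96 ± 2.61. Below Input were Cox6a1, a subunit of cytochrome c oxidase, by -2.16 ± 0.54, the microRNA gene Mir6538 by -1.97 ± 0.77, Pnck by -1.77 ± 0.91, Azgp1 by -1.62 ± 1.39, Acaa2, an enzyme of fatty acid oxidation, by -1.57 ± 0.93, Fetub by -1.33 ± 0.80, Zfp654 by -1.32 ± 1.09, Mup18 by -1.30 ± 0.86 and Serpina1d by -1.29 ± 0.75. Without IgG 1, 2544 genes were below Input in both remaining libraries; without IgG 2 and without IgG 3, 2050 and 2158 were above. In all, 199 genes were above Input in all HuR libraries and below it in all IgG libraries, and 23 were the opposite.

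Genes higher in HuR RIP than in both controls are those the design can call HuR-associated. All 37 genes called against IgG RIP were also above the Input mean in all 3 HuR libraries. Both comparisons share the HuR libraries, so a large overlap arises without any effect: independent lists would share 25.5 genes, and 20 simulated draws with no effect shared 28.5 on average and at most 34. The draws left out the general shift of the data, where 3799 of 5510 tested genes lay above the Input mean in all 3 HuR libraries. They therefore cannot tell whether 37 exceeds what the shared libraries and that shift give. The count followed that of the first comparison as libraries were left out, from 0 without IgG 2 to 1729 without IgG 1.

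HuR is known to bind U-rich and AU-rich RNA, and the 3' UTRs of called genes were therefore searched. Of 3943 tested protein-coding genes, 3932 had an annotated 3' UTR, among them 21 called higher, whose median 3' UTR was 458 nt against 1365 nt in the others. Per 3' UTR, the called genes held 0.333 copies of UUUUUUU, against 1.67 in matched genes (adjusted p = 0.297 over 4 motifs, permutation test; 0.0215 without matching on 3' UTR length). They held 1.48 copies of AUUUA against 1.17 (adjusted p = 0.749; ratio 1.27, but 0.658 without matching and 0.898 per kb), 0.238 of UUUAUUU against 0.276 (adjusted p = 1) and 0.0952 of UAUUUAU against 0.138 (adjusted p = 1). Genes are not independent replicates. In the wider set of 1275 genes higher at an unadjusted p under 0.05, chosen after the data were examined and with a median 3' UTR of 1698 nt against 1226 nt, UUUUUUU was 1.15 times as frequent as in matched genes and AUUUA 1.17 times (both adjusted p = 4e-05, from p = 2e-05, the smallest the permutations can give). UUUAUUU was 1.11 times as frequent (adjusted p = 3.5e-04) and UAUUUAU 1.03 times (adjusted p = 0.452).

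Reads also lay differently along genes. Over 2711 protein-coding genes with reads in every library, the median share of a gene's reads in its last exon was 47.9%, 40.5% and 50.2% in HuR 1, 2 and 3. It was 33.0%, 26.7% and 17.1% in IgG 1, 2 and 3 and 28.4% in the Input mean, so that the groups did not overlap. Summed over these genes, the share was 56.3%, 46.2% and 68.1% in HuR 1, 2 and 3. It was then 30.8%, 43.0% and 39.4% in IgG 1, 2 and 3 and 44.3% in the Input mean, with HuR 2 close to IgG 2. The last-exon share was chosen after Alb was seen. The last exon of Alb (chromosome 5, 90476460 to 90476602) was at 5341, 1313 and 6058 RPKM in HuR 1, 2 and 3 and at 75.4, 17.8 and 236 RPKM in IgG 1, 2 and 3, with 212 RPKM in the Input mean. Its first listed exon (90460897 to 90461013) was at 130, 229 and 70.2 RPKM in HuR 1, 2 and 3 and at 472, 107 and 673 RPKM in IgG 1, 2 and 3.

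**Figure D3:**
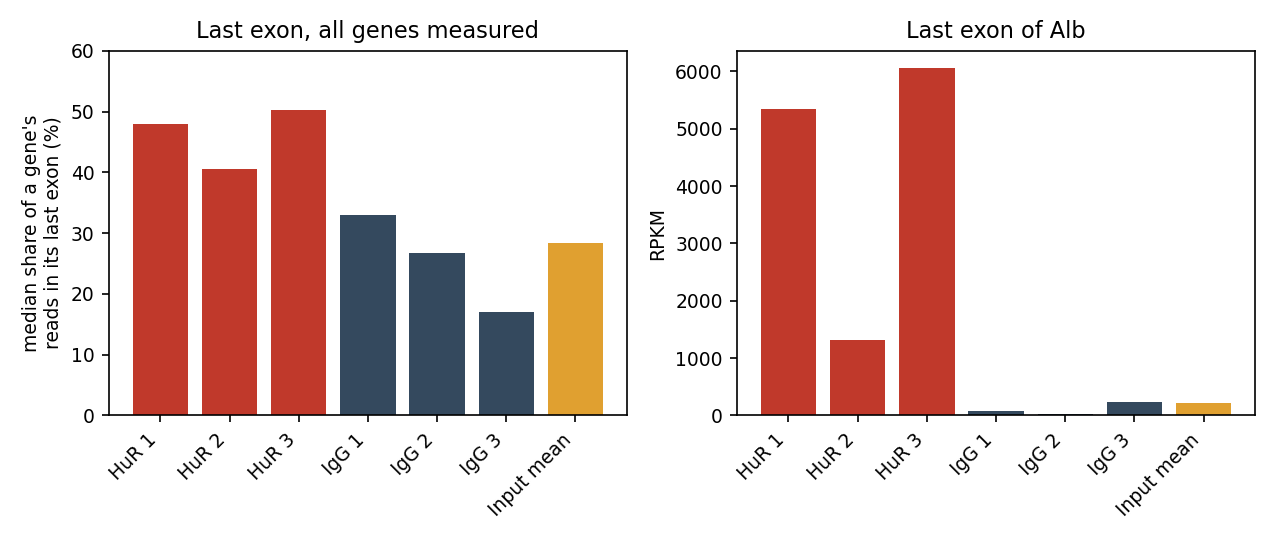
Left, median share (percent) of a gene's reads in its last exon over 2711 genes, per RIP library and for the Input mean (bars); right, level (RPKM) of the last exon of Alb in the same libraries. The share is above 40% in all 3 HuR libraries and at most 33.0% in the IgG libraries.

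Similarity between libraries was compared last. Across tested genes, which are not independent replicates, the Pearson correlation of log2 values was 0.822 to 0.874 between HuR libraries and 0.867 to 0.938 between IgG libraries, and 0.744 to 0.835 between groups. The first principal component held 46.6% of the variance and parted HuR from IgG libraries, with IgG 1 the nearest of the IgG libraries to HuR.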

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

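Of the alternatives in this part, those chosen only after the data were seen are voom, each exon counted once, centring at the median, HuR 3 and IgG 1 both left out, the list tests under other scalings or with protein-coding genes only, and the wider motif set; the others were planned. With 3 libraries a group, simulated changes of 2 on the log2 scale were found in 7% of genes, and genes of few reads, such as Cycs and Ndufb6, fell under the filter and were tested only without it. The 33 tested gene lists kept direction and side of the threshold in 397 comparisons, were weaker in 29, stronger in 7 and reversed in 34. Those stronger were cytochrome P450 enzymes under centring, cholesterol synthesis under centring and with HuR 3 and IgG 1 both left out, fatty acid and triglyceride synthesis with both left out, fatty acid oxidation without HuR 1, cell cycle genes without IgG 1, and red blood cell genes with protein-coding genes only. Named genes did so in 1136, were weaker in 164, stronger in 228 and reversed in 9. Except where said, the cause was not tested.

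Against 37 higher and 7 lower genes, of which 37 were HuR-associated, limma gave as higher, lower and associated: 5, 4 and 5 under quantile normalization; 1, 4 and 1 with scaling without structural RNA; 953, 115 and 924 with the stricter filter, which tested fewer genes (2666); 3, 1 and 3 with a pseudocount of 1; 4, 1 and 4 without trend. It gave 2296, 84 and 2159 with sample quality weights, 147, 4 and 147 with voom on recovered reads, 1, 18 and 1 centred at the median, and 294, 21 and 287 with HuR 3 and IgG 1 both left out. With protein-coding genes only (3943 tested) it gave 728 higher and 698 associated, and with TMM-like scaling 361 lower. No filter (28263 tested) gave 0, 0 and 0, with 1193 higher and 101 lower at an unadjusted p under 0.05. Each exon counted once gave 0, 0 and 0, with 1513 and 161 at that level. Leaving out a library gave 0 to 1761 higher, 0 to 30 lower and 0 to 1729 associated. The median of all genes, 0.92, was 0.0023 under TMM-like scaling, 0.05 under quantile normalization, 0.62 without structural RNA and -0.18 under centring. It was 0.093 with no filter, 1.29 with the stricter filter, 1.08 with protein-coding genes only and 1.93 with voom. The size of the shift thus depended on more than the scaling.

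A replicate block gave 0 higher, 0 lower and 0 associated, with 1665 and 238 at an unadjusted p under 0.05. Deviations of HuR and IgG libraries of the same number correlated by 0.138, 0.117 and 0.086 across genes, against -0.089 to -0.001 for different numbers. The same-number values were the highest but low. Sex-linked RNAs went the other way for numbers 2 and 3 as named. Xist was at 10.2 RPKM in HuR 2 and 0.103 RPKM in IgG 2. Ddx3y was at 2.04 RPKM in HuR 3 and 0 in IgG 3. In both libraries of number 1, Xist was near 0 and Ddx3y was above 0. These IgG levels are low, and the names of HuR 2 and HuR 3 may be exchanged. Whether libraries of the same number share a source therefore stays open.

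The Input counts were 3799 above and 540 below for HuR, and 1138 and 728 for IgG. They became 1631 and 1986 for HuR and 1691 below for IgG under TMM-like scaling; 2230, 1571, 1817 and 1563 under quantile normalization; 1053 below for HuR and 1625 below for IgG without structural RNA. With no filter they were 7171, 4851, 1726 and 6759, with the stricter filter 2157 and 305 for HuR and 361 below for IgG, and with protein-coding genes only 126 below for HuR and 476 and 370 for IgG. Differences of 1 or more left 1841, 257, 469 and 203. Leaving out an IgG library gave 1193 to 2158 above and 861 to 2544 below for IgG, as fewer libraries then have to share a side.

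Of the gene list tests, 7 were past the threshold; 0 were with an estimated correlation, 0 with fry (which does not compare a set with other genes), 4 under quantile normalization and 3 with protein-coding genes only.

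Of the 33 tested lists, those that reversed were not past the threshold in the alternative. With fry they were ribosomal proteins (adjusted p = 0.985), plasma proteins (0.191), endothelial markers (0.198), histones (0.2004), translation factors (0.2445), Kupffer cell markers (0.279) and stellate cell markers (0.294). With protein-coding genes only they were complement and coagulation (0.4295), the respiratory chain (0.534), zinc finger genes (0.625), bile acid genes (0.856) and the proteasome (0.886). Under quantile normalization they were plasma proteins (0.0842) and chromatin regulators (0.6965), under centring plasma proteins (0.916), chromatin regulators and histones (both 0.955), and under TMM-like scaling complement and coagulation (0.704). Without structural RNA they were stellate cell markers (0.804) and complement and coagulation (0.982), and with HuR 3 and IgG 1 both left out translation factors (0.555), plasma proteins (0.728) and zinc finger genes (0.757). With a single library left out, with the range over the libraries whose omission left 5 members or more, they were the respiratory chain without HuR 1 or HuR 3 (0.342 to 0.927), Kupffer cell markers without HuR 1 (0.425 to 0.978), endothelial markers without HuR 1, HuR 3, IgG 1 or IgG 3 (0.578 to 0.945), histones without HuR 1 (0.56 to 0.976), the proteasome without HuR 3 (0.449 to 0.945), complement and coagulation without IgG 2 (0.739 to 0.945) and stellate cell markers without IgG 3 (0.4855 to 0.759). Lists left with fewer than 5 members in an alternative have no value there.

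The motif ratio of UUUUUUU, 0.2 in called genes, was 0.107 without matching on 3' UTR length (adjusted p = 0.0215) and 0.508 per kb (adjusted p = 0.906). In the wider set it was 1.15, or 1.2 per kb. That of UUUAUUU, 0.861, was 0.404 without matching and 0.397 per kb, and in the wider set 1.11 and, per kb, 1.12. That of AUUUA, 1.27, was 0.658 without matching and 0.898 per kb, and in the wider set 1.17 and, per kb, 1.2. That of UAUUUAU, 0.69, was 0.344 without matching and 0.601 per kb, and in the wider set 1.03 and, per kb, 1.02. The wider set holds 1275 genes in place of 21.

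Reversed genes, all under the threshold, were Elavl1 (-0.22), Alb (-0.22), Snhg11 (-0.13), Vsig4 (-0.25), Csf1r (-0.34) and Eng (-0.0024) under centring, Csf1r (-0.28) under quantile normalization, and Alb (-0.75) and C1qa (-0.0018) under TMM-like scaling.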

Other observations

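Of the tests in this part, the comparisons of small nucleolar RNA with small nuclear RNA and, per library, with all genes were chosen only after the result was seen, and so was the use of scaling without structural RNA to test the shift of all genes, although that scaling had been planned as an alternative. Other hepatocyte programmes lay near or above the shift of all genes without being placed apart by camera with all libraries. Urea cycle and amino acid catabolism (21 tested genes) had a median log2 fold change of 1.67, fatty acid and triglyceride synthesis (20) 1.40 (camera adjusted p = 0.0206 with HuR 3 and IgG 1 both left out, but 0.876 with all libraries and an estimated correlation), acute phase proteins (13) 1.40, bile acid synthesis and transport (18) 1.19, gluconeogenesis and glycogen (15) 1.09 and complement and coagulation (29) 1.01. Adjusted over the list alone, 2 acute phase, 2 bile acid and 1 complement gene passed, and 0 of the other lists named here. Circadian clock genes (9) had a median of 1.27, with all 9 above the median of all genes and 2 past the threshold when adjusted over the list alone (camera adjusted p = 0.191).

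Regulatory and housekeeping lists, and those of other cells, were not placed apart either with all libraries and genes. Cell cycle genes (7 tested) had a median of 1.25 (camera adjusted p = 0.0400 without IgG 1, but 0.876 with all libraries and an estimated correlation), immediate early and stress genes (10) 1.10, apoptosis regulators (9) 1.10, C2H2 zinc finger genes (23) 1.05 and chromatin and transcription regulators (13) 0.97. Proteasome subunits (14) had 0.79, translation factors (20) 0.71 and replication-dependent histones (5) 0.55. Stellate cell and matrix markers (7) had 0.27 and red blood cell genes (5) 0.27, with a mean of -0.04 of opposite sign. The camera direction was down for translation factors, histones, stellate cell markers and red blood cell genes. With protein-coding genes only, camera placed red blood cell genes below other genes at the preset correlation (adjusted p = 0.0250); with all genes the adjusted p was 0.876 with an estimated correlation and 0.985 with fry. Cholangiocyte markers (3) had 0.50 and nuclear long non-coding RNAs (3) 1.40, both too few for camera. Mitochondrially encoded mRNAs had 0 genes in the table.

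Most genes were higher in HuR RIP than in IgG RIP, by a median of 0.92. Per library, the median deviation was 0.56, 0.54 and 0.31 in HuR 1, 2 and 3 and 0.20, -0.80 and -0.88 in IgG 1, 2 and 3. A larger share of structural RNA in the IgG reads was tested by scaling on the other genes, which left a median of 0.6172 (SE over libraries 0.22). The structural RNA genes set aside could thus account for part of the shift but not for all of it. Reads of small nucleolar RNA counted on exons of other genes stayed in that scaling, as did microRNA genes. A larger part from structural RNA therefore stays open. Genes missing from IgG libraries of low complexity were tested on the 3758 genes above 0 in all 6 libraries. Their median was 0.8687 (SE over libraries 0.34). These genes had first passed the filter at 0.5 RPKM. That level was reached by 7320, 7854 and 6999 genes in HuR 1, 2 and 3, against 6507, 2788 and 3076 in IgG 1, 2 and 3. More genes could thus enter through the HuR libraries, so the test cannot tell whether low complexity gives the shift. A real excess of mRNA held by HuR and a different total amount of RNA in the pull-downs both stay open, as RPKM carry no absolute scale. For the 44 calls, 1 of the 10 splits of the 6 libraries gave as many, the real one, and the highest other gave 1; 10 splits are too few for a share under 0.05.

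Small nucleolar RNAs were lower in HuR RIP than in IgG RIP, although their median was above Input in both, by 2.09 and 3.94 on the log2 scale. A loss of short structural RNA from the HuR libraries that is blind to class would take small nuclear RNA alike. The difference between both classes was 3.83, 3.92 and 3.92 in HuR 1, 2 and 3 and 0.93, 1.49 and 2.70 in IgG 1, 2 and 3. This gap of 1.135 between the groups argues against a loss that takes both classes alike. A loss that depends on RNA length was not tested. The 5S copy n-R5s71 and the U3 copies, listed here as small nuclear RNA, also had negative log2 fold changes. IgG 1 as the sole source of the place below other genes is argued against: relative to all genes, the list lay at 5.16, 3.84 and 4.23 in HuR 1, 2 and 3 and at 6.64 and 6.24 in IgG 2 and 3, a gap of 1.087 without IgG 1. For the lower level itself IgG 1 cannot be told apart, since without it the median was -0.6187, between the bounds set beforehand. Carry-over of small nucleolar RNA by IgG was not tested otherwise. The lower place of ribosomal protein genes may come from small nucleolar RNA reads counted on exons that cover them: the 31 genes without such an exon lay at -0.1936 relative to the median of all genes, and the 20 with one at -2.20.

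A hypothesis concerns 31 nuclear copies of mitochondrial genes, whose RNA may be that of mitochondria, which has no place in the table. Across copies, identity to the mitochondrial genome and mean RPKM had a Spearman rho of 0.8852 (permutation p = 1e-05, the smallest it can give; copies are not independent replicates). The 11 copies at 95% identity or more had a median of 215 RPKM and the 20 others one of 0.144 RPKM. In reads scaled to library size (RPM), the copies took 3478, 1822 and 2764 in HuR 1, 2 and 3 and 478, 157 and 199 in IgG 1, 2 and 3. All 13 tested copies had positive log2 fold changes (median 2.86), and 1 of them, Gm13341, was past the threshold, at 330 ± 233 RPKM against 4.35 ± 1.80 RPKM (SD, n = 3 each; adjusted p = 0.0237). Gm13341 is a copy of mt-Co2 at 95.9% identity. Gm28661, a copy of the same gene at 100% identity, was at 691 ± 263 RPKM in HuR RIP and 106 ± 78.9 RPKM in IgG RIP (SD, n = 3 each). Its log2 fold change was 2.86, against 5.68 for Gm13341. Whether reads of 1 mitochondrial RNA give both copies was not tested. Why RNA listed on these copies was higher in HuR RIP was not tested either.

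A second hypothesis started from the last exon of Alb: that HuR RIP holds more of the 3' ends of mRNAs. The lowest HuR library exceeded the highest IgG library in the median last-exon share by 7.53 percentage points. This may reflect fragments held by HuR on 3' UTRs or a 3' bias of the HuR libraries that is blind to sequence. For AUUUA, the excess of AUUUA-rich over AUUUA-poor genes in last-exon share was 3.79, 2.14 and 4.29 points in HuR 1, 2 and 3 and 2.29, 0.82 and -0.56 points in IgG 1, 2 and 3. The lowest HuR minus the highest IgG value was -0.1497, an overlap that sequence-blind bias predicts. For UUUUUUU the excess was 1.62, 1.80 and 1.02 points in HuR 1, 2 and 3 and 1.43, -0.67 and 2.12 in IgG 1, 2 and 3, with a gap of -1.098, again an overlap. For UUUAUUU it was -1.001, -1.25 and -0.13 against 1.02, 0.38 and -3.90, and for UAUUUAU -1.23, -0.88 and 0.25 against -0.79, -0.79 and -3.31, so that both also overlapped. With 3 libraries a group, HuR held on U-rich and AU-rich 3' UTRs stays open and cannot be told apart from that bias.

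RNAs of the sex chromosomes differed between libraries of a group, so a group may hold livers of both sexes. No comparison took this into account. Xist, on the X chromosome, was at 0.0021, 10.2 and 0.463 RPKM in HuR 1, 2 and 3 and at 0.0070, 0.103 and 0.359 RPKM in IgG 1, 2 and 3. Eif2s3y, on the Y chromosome, was at 1.40, 0 and 0.868 RPKM and at 0.537, 0.247 and 0 RPKM, and Ddx3y at 0.429, 0.0188 and 2.04 RPKM and at 0.328, 0.0558 and 0 RPKM. The RPKM column names carry an M for HuR 1, HuR 2, IgG 1 and IgG 2 and an F for HuR 3 and IgG 3, letters that the labels do not explain, and the authors' fold columns number HuR 2 and HuR 3 the other way round. If the names of these 2 libraries were exchanged, values without HuR 2 and without HuR 3 would change places and the replicate block would join other libraries, while the groups would stay as they are.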
